A study of Drosophila melanogaster with 9 samples.

How the data were processed

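RNA was measured in 3 cell populations sorted from Drosophila brains without optic lobes. These were Kenyon cells (KC), which carried GFP, olfactory projection neurons (PN), which carried tomato, and cells negative for both (double negative, DN). Brains were taken at 45 h after puparium formation (45 h APF) and from adults. Per the labels, the series holds 9 libraries, 1 per cell type at 45 h APF (each from a pooled sample) and 2 per cell type in the adult. PolyA RNA was made into libraries with SmartSeq version 2, with about 1 ng of RNA as the aim, and amounts were matched across the cell types of a replicate. Adult libraries were read for 50 bases on a HiSeq and pupal libraries for 75 bases on a NextSeq, so stage, sequencer and read length cannot be told apart.

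The deposited values were FPKM (fragments per kilobase of transcript, scaled to the mapped reads) made by the authors. TopHat, Cufflinks and the genome build dm6 are named in the submitters' processing notes, without versions. The table holds 1 column for each pupal library, and for the adult 1 column per cell type, in which the authors had averaged the replicates. The adult replicates were not in the file, so every adult value below is the authors' mean, with no standard deviation. Read counts were not used here. The column sums were 1055098, 979179 and 886258 FPKM for KC, PN and DN at 45 h APF and 720834, 704373 and 611610 FPKM for the adult. Smallest steps between values of the pupal columns correspond to about 24.2, 29.2 and 32.3 M reads for KC, PN and DN, an inference that puts 88.5%, 92.6% and 92.3% of the low values within 0.1 of a whole number of reads. It assumes an effective length 200 bases shorter than the transcript. The labels give 25 M reads as the planned depth. The depth behind the adult means cannot be read from the values, and no counting intervals are given.

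The table had 16859 lines. In 5 of these the gene name had been turned into a date, and they were left out, which left 16854 genes. Names were matched to Ensembl annotation release 115, 12785 by symbol and 3900 by synonym, and 169 were unmatched. Of the matched genes, 99.0% overlapped the locus the table gives. Many genes (8045) share a locus string with another gene, and 129 genes are listed at 0 in 1 column and at 50 FPKM or more in another, 99 of them short noncoding genes. Whether these zeros are absence or a failed estimate is not stated, so no fold is given against a column listed at 0.

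Values were analysed as log2(FPKM + 1). Within a stage, genes with a mean of at least 1 FPKM over the 3 columns were kept (8603 at 45 h APF and 8515 in the adult). With 1 value per cell type and stage, comparisons within a stage are sizes with no test of single genes. Counts are of genes that differed at least 4-fold on this scale, and of list members that differed at least 2-fold. Before the data were examined, 34 gene lists with 618 genes were fixed, covering cell type markers, cell surface families, transmitters, receptors, channels, signalling, stress and housekeeping genes, of which 2 genes have no line in the table. The 153 genes of all the cell surface families together form the cell surface list. Each list median was set beside 10000 random lists of other genes drawn from the same 20 bins of mean expression, and their 2.5th to 97.5th percentiles are given as the matched range. A second draw also matched 5 bins of exon length. Lists with fewer than 5 kept genes got no range. A gene was called detected at 5 FPKM or more.

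Effects common to both stages, and the stage effect common to the 3 cell types, were tested with limma 3.58.1 in R 4.3.3, in an additive model of cell type and stage with a mean-variance trend, over the 6 columns (8867 genes). It has 2 residual degrees of freedom and a prior of 4.1. Its p-values set each effect against the residual spread, which is how far cell type differences changed between the stages. They do not measure variation between replicate animals. P-values were adjusted by the method of Benjamini and Hochberg, with a threshold of 0.05. Lists of at least 5 genes were tested with camera at a correlation of 0.01, again with an estimated correlation, and with fry. No list call of camera at 0.01, in any of the 4 contrasts, held with an estimated correlation or with fry. Both checks have little power with 2 residual degrees of freedom. Even the Kenyon cell list for KC minus PN, with an estimated correlation of 0.071, had adjusted p-values of 0.521 (camera) and 0.234 (fry). A lost call therefore does not show that a list was unshifted, and the calls at 0.01 rest on that preset correlation. On simulated data with 200 changed genes, 22% to 23% of genes changed by 2 on the log2 scale and 90% to 91% of those changed by 4 were recovered in the cell type contrasts, and 54% and 93% in the stage contrast. Of 124, 126 and 120 calls for KC minus PN, KC minus DN and PN minus DN, 11, 14 and 6 were false, and of 153 for the stage 6 were. Of 300 random lists of 30 genes, 5.7% fell outside the matched range with no shift and 89.0% with a shift of -1. The simulated genes varied independently, whereas the estimated correlation was 0.25 for the cell surface list and 0.932 for the pan-neuronal list. These shares therefore do not tell how often a list of correlated genes leaves its matched range.

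The named genes followed a rule fixed before the data were examined. It took 15 marker genes in each comparison, the 10 called genes with the largest difference in each direction of each contrast, provided the groups did not overlap, and for each comparison within a stage the 10 largest differences in each direction among genes of at least 10 FPKM in the higher column. From each list it took up to 4 members with the largest difference in that contrast, and members set beside another comparison of the same gene. For adult comparisons, the rule for the pupal ones was used because the averages allow no test. Genes listed at 0 in a column of the comparison were left out of the largest differences.

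The alternatives were pseudocounts of 0.1 and 5, no filter and a mean of at least 5 FPKM, quantile normalization, upper quartile scaling, detection at 1 or 20 FPKM, no trend in limma and leaving out each column. Added after seeing the data were protein-coding genes only, genes above 0 in all 6 columns, and a weight of 2 for the adult means. Quantile normalization moved the median of all genes for KC minus PN from 0.02 to 0.11 at 45 h APF and from 0.01 to 0.14 in the adult. Upper quartile scaling moved it for KC minus DN from 0.02 to -0.15 and from 0.03 to -0.08. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 did the rest.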

Results

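The deposited FPKM columns were compared, 1 for each of KC, PN and DN at 45 h APF and 1 for each in the adult. Kenyon cells are the intrinsic neurons of the mushroom body, the centre of olfactory learning in the fly, and projection neurons bring them odor signals from the antennal lobe. Each pupal value is from 1 library and each adult value is the authors' mean, with 2 libraries in the labels, so there is no error for single values. Between 7746 (KC, adult) and 8646 (DN, 45 h APF) genes reached 1 FPKM. The noncoding gene CR40469 took the most FPKM of the KC column at 45 h APF (128393 FPKM), and the 10 highest genes took 27.8% of that column and 7.5% of the adult DN column.

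Markers of each population were measured to ask whether the sorted cells carried the genes of their type. The eyeless gene ey (chromosome 4, 697689 to 721173, dm6), a transcription factor of Kenyon cells, stood at 228 FPKM in KC, 1.21 in PN and 5.42 in DN at 45 h APF, and at 275, 0.143 and 7.58 in the adult. The transporter gene prt (chromosome 3R, 23696372 to 23699027), known from Kenyon cells, stood at 532 FPKM in pupal KC against 2.89 in PN and 4.86 in DN, and at 439 in adult KC against 0.291 and 11.8. The transcription factor dac, also of Kenyon cells, was at 42.9 FPKM in pupal and 86.0 in adult KC, with 4.48 and 5.29 in PN. The zinc finger gene Oaz (now named L; chromosome 2R, 14435899 to 14465881), expressed in projection neurons, was at 66.0 FPKM in pupal and 172 in adult PN, at 0.128 and 0 in KC, and at 0.168 and 0.255 in DN. For acj6, a POU factor of some projection neurons, the PN values were 7.05 and 43.2 FPKM and the KC values 0.178 and 0.090. By contrast Mef2, a Kenyon cell factor at 49.7 FPKM in pupal KC and 4.71 in PN, stood at 125 in adult KC and 112 in adult PN. The other PN marker, vvl, was at 0.860 FPKM in pupal PN and 5.74 in adult PN, beside 4.10 and 5.24 in DN. Among transmitter genes in the adult, ChAT, which makes acetylcholine, was at 89.8, 648 and 171 FPKM in KC, PN and DN, and Gad1, which makes GABA, at 25.1, 762 and 994. VGlut, the vesicular glutamate transporter, was at 3.85, 20.9 and 124 FPKM, and the neuronal gene elav at 83.4, 91.1 and 36.2. Markers of glia were also present: repo, the glial transcription factor, was at 6.42, 29.9 and 12.3 FPKM in KC, PN and DN at 45 h APF, and at 0.480, 0.347 and 1.82 in the adult.

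**Figure D1:**
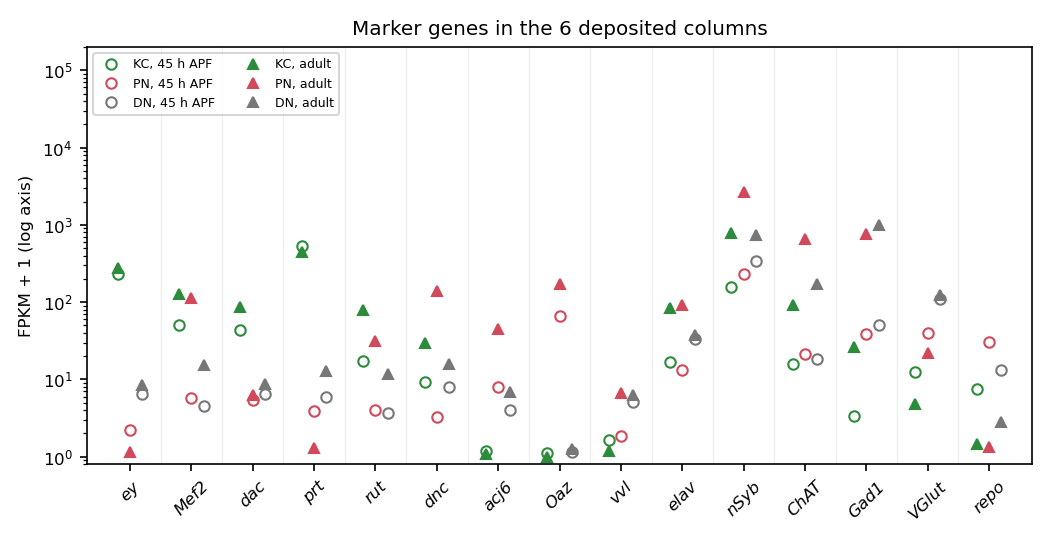
FPKM + 1 on a log axis for 15 marker genes, with open circles for 45 h APF, filled triangles for the adult, and colors for KC, PN and DN. For ey and prt both KC values lie above every PN and DN value, and for Oaz both PN values (66.0 and 172 FPKM) lie above the rest.

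The title of the study names depletion of cell surface molecules, so the number of cell surface genes detected in each population was counted. Of 153 cell surface genes, 65 reached 5 FPKM in KC at 45 h APF, against 100 in PN and 123 in DN. In the adult the counts were 74, 119 and 117. KC thus had 65.0% as many as PN and 52.8% as many as DN at 45 h APF, and 62.2% and 63.2% in the adult. These counts are for each sorted population as a whole and not for single cells. Over all genes in the table, the share that reached 5 FPKM was 37.2%, 40.0% and 40.7% for KC, PN and DN at 45 h APF and 38.5%, 40.6% and 40.1% in the adult. At 45 h APF, 66 of 139 kept cell surface genes were at least 2-fold lower in KC than in both PN and DN, and 1 was higher than in both. In the adult 54 of 133 were lower and 1 was higher. The random lists matched on expression had medians of 19 and 11 such genes and maxima of 36 and 25. Of the 132 genes kept at both stages, 45 were lower at both, where 26.2 would be shared if the stages were independent. By family, the counts at 45 h APF and in the adult were 16 and 18 of 32 for the dpr and DIP genes, a network of binding partners with immunoglobulin domains, and 13 of 22 at each stage for the beat and side genes. They were 20 of 37 and 12 of 35 for the other immunoglobulin genes, 7 of 18 and 5 of 16 for leucine-rich repeat genes, 5 of 8 and 3 of 7 for cadherins, and 9 of 22 and 5 of 21 for guidance genes. The teneurin, neurexin and neuroligin genes gave 1 and 2 of 7. The guidance list shares members with others, such as robo2, robo3 and sli, so the family counts overlap. Of all kept genes, 11.5% at 45 h APF and 7.9% in the adult were lower in KC than in both. Counts inside the range of matched lists were those of teneurin, neurexin and neuroligin genes (0 to 3 and 0 to 2), adult guidance genes (0 to 5) and adult cadherins (0 to 3).

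**Figure D2:**
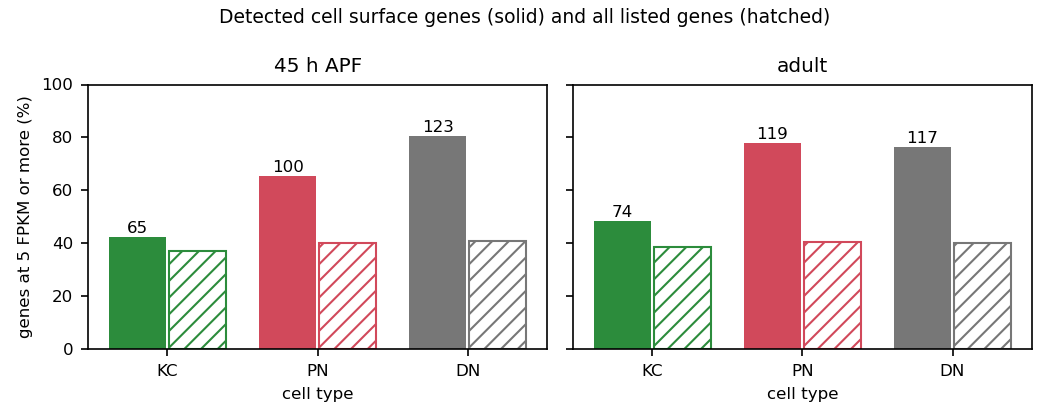
Percent of genes at 5 FPKM or more in KC, PN and DN at 45 h APF and in the adult, for the 153 cell surface genes (solid bars, with their number) and for all genes of the table (hatched bars). The solid KC bars, 42.5% and 48.4%, are the lowest of each stage, while the hatched bars lie between 37.2% and 40.7%.

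At 45 h APF, KC and PN were compared to ask how the 2 partners of the mushroom body input synapse differ while the circuit forms. The nuclear receptor gene Hr51 was at 281 FPKM in KC and 0.018 in PN, a log2 difference of 8.11, and the peptide hormone gene Akh at 512 against 2.07 (7.38). Genes of cyclic AMP signalling, a pathway of olfactory learning, had a median difference of 1.51 with 8 of 15 at least 2-fold higher in KC (matched range -0.95 to 0.41), among them the protein kinase A genes Pka-R2 (3.78), Pka-C1 (3.16) and Pka-R1 (3.07). Kenyon cell genes had a median of 1.89, with 14 of 17 higher and 2 lower, and projection neuron genes -2.77, with 6 of 7 lower. The Kenyon cell and cyclic AMP lists both hold rut, dnc and Pka-C1, so their medians are not independent. Cell surface genes had a median of -1.08 (matched range -0.25 to 0.11), with 75 of 139 lower in KC and 8 higher. The lowest in KC was DIP-eta, at 0.424 FPKM against 33.0 in PN (-4.58), followed by dpr18 (-4.34), beat-IIb (-3.97) and dpr11 (-3.78). Glial genes, with a median of -2.45 and 10 of 14 lower in KC, included alrm, an astrocyte gene, at 9.70 FPKM in KC and 388 in PN, and Gat, a GABA transporter of glia, at 2.37 and 82.4. In all, 198 of 8603 genes were at least 4-fold higher in KC and 607 lower, which makes 75.4% of the differences lower in KC, and 64.4% with quantile normalization (238 higher and 430 lower). With a pseudocount of 5 the total of 805 became 355 and the cell surface median became -0.61, and with 0.1 the total became 1293.

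KC and DN at 45 h APF set Kenyon cells against the cells of the central brain that were negative for both labels. Neuropeptide genes stood lower in KC, with a median of -2.66 and 19 of 26 at least 2-fold lower (matched range -0.85 to 0.20). SIFa was at 0.261 FPKM in KC and 59.7 in DN, and Dh31 (-4.72), Pdf (-4.50) and Ms (-3.80) followed. Genes for making and handling monoamines had a median of -1.90, with 5 of 7 lower and DAT, the dopamine transporter gene, higher (207 against 40.9 FPKM). For the cell surface list the median was -1.76 (matched range -0.36 to 0.08), with 93 of 139 lower and 1 higher. Members were dpr18, at 2.29 against 118 FPKM (-5.18), beat-Ib (-4.34), beat-Ia (-4.01) and dpr11 (-3.96). Genes of muscle stood higher in DN than in KC and PN, with Mlc1 at 0.683 FPKM in KC and 34.4 in DN, and their median was -3.71 over 5 genes. The Kenyon cell list had a median of 1.18, with 10 of 17 higher, and the heat shock list 0.72, with 4 of 15 higher. Glial genes had a median of -0.94 (matched range -0.61 to 0.50), with 7 of 14 lower and none higher. Pan-neuronal genes were lower in KC as well, with a median of -1.07 (matched range -0.97 to 0.51), 7 of 11 at least 2-fold lower and none higher. Genes at least 4-fold apart numbered 150 higher and 555 lower in KC, or 220 and 387 with quantile normalization and 124 and 674 with upper quartile scaling. That total of 705 became 1201 with a pseudocount of 0.1 and 248 with 5, the share lower moved from 78.7% to 68.1% with 5, and the cell surface median moved to -1.02.

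**Figure D3:**
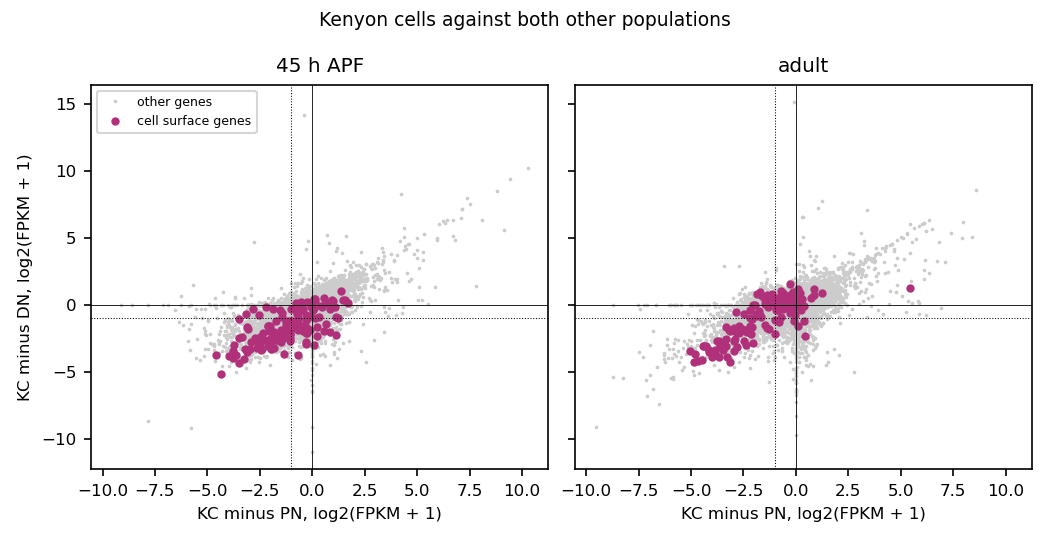
Difference in log2(FPKM + 1) of each kept gene between KC and PN (horizontal) and between KC and DN (vertical), at 45 h APF and in the adult, with cell surface genes in magenta and other genes in grey. The 66 and 54 cell surface genes to the left of and below the dotted lines at -1 were at least 2-fold lower in KC than in both.

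PN and DN at 45 h APF differed in fewer genes, 169 higher and 241 lower in PN. The gene CG9336 (now bero) was at 2318 FPKM in PN and 15.4 in DN (7.14), and CG9691 at 813 against 5.81 (6.90), with KC at 44.5 and 9.73. Glial genes had a median of 1.12 with 8 of 14 higher in PN and 2 lower (matched range -0.24 to 0.32), among them moody, a gene of the blood-brain barrier, at 41.1 against 5.42 FPKM, while wrapper was at 14.1 against 43.0. Neuropeptides had a median of -1.35, with 15 of 26 lower in PN, and muscle genes -4.17, with Act87E at 0.0249 against 116 FPKM. The cell surface list had a median of -0.52 (matched range -0.09 to 0.13), with 38 of 139 lower, such as Cals, a cadherin (-3.32), and 10 higher. The total of 410 genes became 652 with a pseudocount of 0.1 and 154 with 5, and the share lower in PN fell from 58.8% to 44.8% with 5.

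Adult KC and PN were compared with the same question for mature cells. The transcription factor gene otp was at 0.176 FPKM in KC and 212 in PN (-7.50) and mirr at 0.133 against 141 (-6.97), while the neuropeptide gene sNPF was at 1343 FPKM in KC and 8.68 in PN (7.12). Over the cell surface genes the median was -1.45 (matched range -0.17 to 0.24), with 78 of 133 at least 2-fold lower in KC and 2 higher. DIP-eta (-5.06), DIP-theta (-4.87) and rdo (-4.79) were low in KC, and Lac was high (46.1 against 0.0777 FPKM, 5.45). Genes of the neuronal machinery, such as para, the sodium channel (-3.65), and Syx1A, a fusion protein of synaptic vesicles (-3.57), had a median of -2.06, with 10 of 11 lower in KC. The voltage-gated and potassium channels had -1.58, with 15 of 23 lower, including SK (-4.51). Heat shock genes had a median of 1.5, with 10 of 14 higher in KC and Hsp70Bbb at 30.7 against 0.393 FPKM, and ribosomal protein genes 0.81, with 22 of 85 higher. Of 8515 genes, 223 were higher and 690 lower in KC by 4-fold or more (67.8% lower with quantile normalization, 75.6% without). With a pseudocount of 5 the total of 913 became 434, and all genes in the fifth with the longest exons had a median of -0.64.

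Among lists with at least 5 kept genes, neuropeptides had the lowest median between adult KC and DN, with a value of -3.63 and 22 of 28 lower in KC (matched range -0.41 to 0.27). Orcokinin was at 0.283 FPKM in KC against 66.2 in DN (-5.71), Capa at 5.75 against 220 (-5.04) and FMRFa at 0.255 against 39.9 (-5.03). The kinase gene Src64B was at 1637 FPKM in KC and 11 in DN (7.09), and Kenyon cell genes had a median of 2.66, with 15 of 16 higher. Genes of monoamine neurons had -2.93, with 6 of 7 lower, such as Vmat (5.43 against 123 FPKM). Cell surface genes had a median of -0.70 (matched range -0.07 to 0.18), with 60 of 133 lower, including DIP-theta (-4.29), beat-IIa (-4.28) and robo3 (-4.15), and 5 higher. Its families spread from -1.99 for beat and side and -1.70 for dpr and DIP to 0.03 for guidance genes, a sign that upper quartile scaling turned to -0.10. Heat shock genes had a median of 1.61, with 12 of 14 higher in KC, and glial genes -1.47, with 8 of 9 lower. At least 4-fold, 189 genes were higher and 442 lower, or 217 and 357 with quantile normalization. A pseudocount of 0.1 took this total of 631 to 988 and 5 took it to 276, with 59.4% in place of 70.0% lower, and the cell surface median was -0.46 with 5 and -0.38 with no filter or with a filter of 5 FPKM.

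Adult PN and DN differed with more genes higher than lower in PN, 377 against 257. Pan-neuronal genes had a median of 2.26, with 10 of 11 at least 2-fold higher in PN, and the channel list 1.71, with 17 of 23 higher, such as SK (155 against 14.3 FPKM) and para (65.4 against 8.43). Glial genes stood lower in PN, with a median of -1.34 and 6 of 9 at least 2-fold lower (matched range -0.61 to 0.83). Neuropeptides had a median of -3.45, with 22 of 28 lower in PN, and monoaminergic genes -3.49, where DAT was at 0.652 against 75.4 FPKM. Cyclic AMP genes had a median of 1.30, with 11 of 17 higher, and dnc, a phosphodiesterase gene of learning, was at 137 against 14.9 FPKM. The cell surface list had a median of 0.58, with 46 of 133 higher, among them Dscam4 (2.66) and Cals (2.65), and 7 lower, among them Lac (-4.17). Long genes stood higher in adult PN in general, with a median of 0.77 in the fifth with the longest exons and -0.21 in the fifth with the shortest. Against lists matched on exon length as well, the cell surface median lay inside the range (0.24 to 0.61), and the pan-neuronal and channel medians lay above theirs (0.13 to 1.64 and 0.20 to 1.1). A pseudocount of 5 took the total from 634 to 307.

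**Figure D4:**
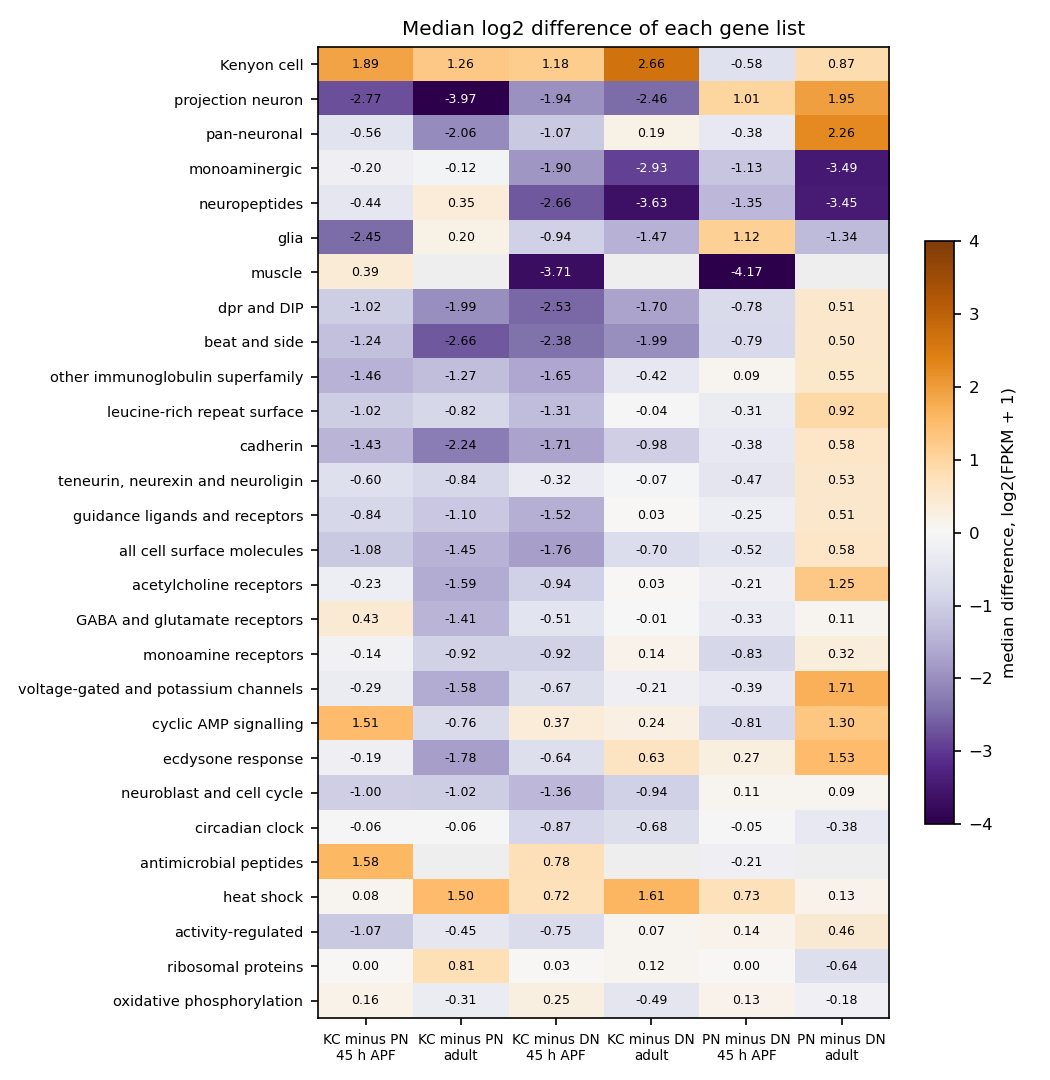
Median difference in log2(FPKM + 1) of each gene list (down) in each comparison and stage (across), in purple where the first population was lower and in orange where it was higher, with empty cells for fewer than 5 kept genes. The cell surface list is at -1.08, -1.45, -1.76 and -0.70 in the KC columns and at -0.52 and 0.58 for PN minus DN.

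The stages were then set side by side, over 7778 genes kept at both. For KC minus PN, 66 genes were at least 4-fold higher at both stages where independence gives 3.5, and 152 lower where it gives 29.1, and 14 went opposite ways. For KC minus DN these counts were 57 (2.3), 222 (21.9) and 11. For PN minus DN they were 18 (3.7), 38 (4.4) and 42. Across genes, which are not independent replicates, Pearson's r between the stages was 0.48, 0.50 and 0.01.

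In the limma fit over both stages, ey was higher in KC than in PN by 7.30 on the log2 scale (SE 0.50, Benjamini-Hochberg adjusted p = 0.00783), prt by 7.75 (SE 0.66, adjusted p = 0.0155) and Hr51 by 7.47 (SE 0.56, adjusted p = 0.0101), each at both stages. The heparan sulfate sulfatase gene Sulf1 was lower (-5.76, SE 0.39, adjusted p = 0.00783), as were the homeobox genes otp (-6.10, SE 0.73, adjusted p = 0.03), mirr (-5.53) and C15 (-5.12). Of 138 cell surface genes, 12 were lower in KC and none higher, 44 and none when adjusted over the list alone. They were dpr1, dpr2, dpr11, dpr18, DIP-epsilon, DIP-eta, DIP-theta, beat-Ib, beat-IIa, beat-IIb, robo2 and robo3, with DIP-eta (chromosome 2L, 5601723 to 5617946) the lowest at -4.82 (SE 0.45, adjusted p = 0.02). The list's camera adjusted p was 4.94e-16, and the adjusted p was 0.521 with an estimated correlation. In the Kenyon cell list ey, dac, prt and jdp of 17 were higher, 8 when adjusted over the list alone (camera adjusted p = 1.42e-07, and adjusted p = 0.521 with an estimated correlation). Among 8867 genes, 27 were higher and 43 lower, with 1378 at an unadjusted p under 0.05. With no filter on low values no gene was called, quantile normalization gave 22 higher and 21 lower, and a pseudocount of 5 gave 28 in all. With 1 column left out at a time, the 70 genes became 0 without any of the 45 h APF columns, 12 without adult KC and 13 without adult DN.

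Against DN over both stages, KC had lower Gad1 (-4.58, SE 0.43, adjusted p = 0.0301), VGlut (-3.92, SE 0.46, adjusted p = 0.0325) and the neuropeptide genes Pdf (-4.19), NPF (-4.11), Ms (-4.04) and Nplp1 (-3.80), each at both stages, and higher prt (5.81, SE 0.66, adjusted p = 0.0316), GstD11 (6.17) and Src64B (5.54). For neuropeptides 4 of 28 were lower, 15 when adjusted over the list alone (camera adjusted p = 2.09e-12, and adjusted p = 0.466 with an estimated correlation). Of 138 cell surface genes 10 were lower, 40 when adjusted over the list alone, and none higher. These were the genes named for PN without DIP-epsilon and robo2, and dpr18 (chromosome X, 16063738 to 16070304) was the lowest at -4.54 (SE 0.44, adjusted p = 0.0301). The list had a camera adjusted p of 5.18e-18, and an adjusted p of 0.466 with an estimated correlation. Among all genes 26 were higher and 41 lower, with 971 at an unadjusted p under 0.05. With no filter on low values 1 gene was called, quantile normalization gave 20 and 16, and a pseudocount of 5 gave 17 in all. The 67 became 0 without DN at 45 h APF, 1 without KC or PN at 45 h APF or without adult DN, 12 without adult KC and 143 without adult PN.

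Between PN and DN, limma called w, the eye color gene, higher in PN (4.66, SE 0.32, adjusted p = 0.0239), and the noncoding gene noe, which is listed at 0 in both DN columns and at 24920 and 39008 FPKM in PN; noe was named after its values were seen. No gene was called lower, and 341 genes had an unadjusted p under 0.05. Adjusted over the list alone, 13 of 28 neuropeptide genes were lower in PN (median -2.16, camera adjusted p = 5.29e-18), 3 of 7 monoaminergic genes were lower (median -2.73, camera adjusted p = 2.25e-05) and 3 of 8 projection neuron genes higher (median 1.29, camera adjusted p = 0.000499), and each of these lists had an adjusted p of 0.828 with an estimated correlation. The cell surface list had a camera adjusted p of 0.539, with a median of 0.06 and no gene called over the list alone. Without adult PN 7 genes were called, without DN at 45 h APF none, and 1 without each other column. The cell surface camera p was then 0.00577 in the lower direction without adult PN and 0.000513 without adult DN, and it was 0.00103 and 0.00018 without PN and DN at 45 h APF.

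The stages were compared to ask what the 3 cell types shared in going from 45 h APF to the adult. Obp44a, an odorant binding protein gene, was at 2514, 2728 and 2871 FPKM in KC, PN and DN at 45 h APF and at 10.4, 4.67 and 17.5 in the adult, a difference of 7.99 (SE 0.36, adjusted p = 0.00119 in limma). Each gene named here had the same direction in all 3 cell types. Ribosomal protein genes were higher at 45 h APF in 70 of 85 cases, with a median of 1.34 (RpL10Ab 2.28, SE 0.25, adjusted p = 0.0069), as were 10 of 15 heat shock genes, led by Hsp67Bc (6.07, SE 0.65, adjusted p = 0.00633). Higher in the adult were 9 of 11 pan-neuronal genes (median -2.43), such as Syt1 (-3.28, SE 0.71, adjusted p = 0.0246), 14 of 24 channel genes such as Sh (-2.75), with Irk3 in the other direction (4.57), and 8 of 16 cyclic AMP genes such as rut, an adenylyl cyclase (-2.28, SE 0.39, adjusted p = 0.0147). Receptor genes called higher in the adult were 2 of 11 for acetylcholine receptors and 5 of 12 for GABA and glutamate receptors, with 1 in the other direction. The counts were 5 of 16 for monoamine receptors and 4 of 28 for neuropeptides. Adjusted over the list alone they were, in that order, 6, 5 with 2 in the other direction, 7 and 3. All 3 cholinergic genes were higher in the adult, with ChAT at -3.57 (SE 0.48, adjusted p = 0.00953), and so was Gad1 (-3.86, SE 0.35, adjusted p = 0.00489). The glial genes zyd (5.09), Cyp4g15 (5.06), wrapper (4.77) and repo (3.03, SE 0.58, adjusted p = 0.0193) of 13 were higher at 45 h APF. Cell surface genes were higher at 45 h APF in 10 of 138 cases, among them Ama (4.18) and babos (3.23), and lower in 6, among them beat-VII (-3.23) and Nrx-1 (-2.85).

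Over those lists the adjusted counts over the list alone were 79 for ribosomal proteins, 11 higher and 1 lower for heat shock, 11 lower for pan-neuronal, 19 lower and 2 higher for channels, 12 lower for cyclic AMP, 4 higher for glia, and 3 higher and 1 lower for cell surface genes. Camera gave adjusted p-values of 3.81e-16 for ribosomal proteins, 1.52e-06 for pan-neuronal genes, 8.84e-07 for channels and 3.94e-06 for cyclic AMP, and each had an adjusted p of 0.677 with an estimated correlation. For heat shock (0.00151) and glia (0.00636), both higher at 45 h APF, the adjusted p was 0.697 and 0.677 with an estimated correlation. Camera placed the cell surface list lower at 45 h APF (median -0.35, adjusted p = 0.00636), although more of its called genes were higher, and the adjusted p was 0.703 with an estimated correlation. The fit called 1505 genes higher and 712 lower at 45 h APF, with 3811 at an unadjusted p under 0.05, and these differences include those between sequencers and read lengths. Glial genes were among those higher at 45 h APF, and how much of the stage difference came from glial RNA in the columns was not tested. The excess of higher genes depended on scaling, with 950 higher and 897 lower after upper quartile scaling and 956 and 766 after quantile normalization. The 2217 became 617 with no filter. They became 0 without DN, 22 without PN and 451 without KC at 45 h APF, and 1124 and 599 without adult KC and PN.

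**Figure D5:**
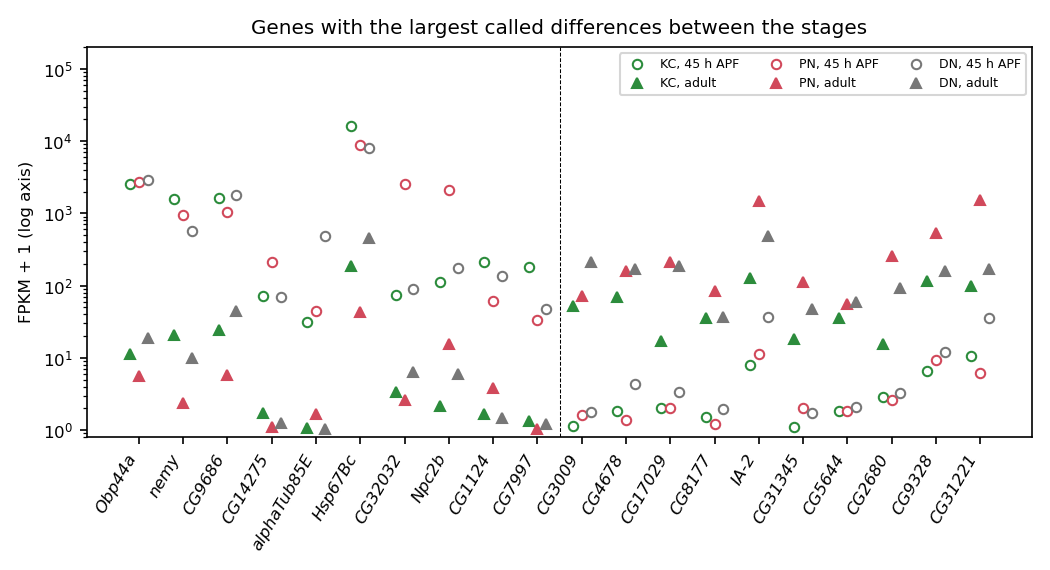
FPKM + 1 on a log axis in the 6 columns for the 20 genes with the largest called stage differences, 10 higher at 45 h APF to the left of the dashed line and 10 higher in the adult to the right, with open circles for 45 h APF and filled triangles for the adult. For Obp44a the 45 h APF values are 2514 to 2871 FPKM and the adult values 4.67 to 17.5.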

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

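The tests of gene detection, of glial RNA among the cell surface genes and of other splits of the columns were chosen after the results they bear on had been seen. The differences between the stages listed here were not tested, since each rests on 1 value per cell type and stage. Gene groups are given where their median had opposite signs at 45 h APF and in the adult and a size of at least 0.5 at each, and marker genes with a size of at least 1, so smaller changes of sign are not listed. For PN minus DN, the median went from -0.58 to 0.87 for the Kenyon cell list, from 1.12 to -1.34 for glia, from -0.78 to 0.51 for dpr and DIP, from -0.79 to 0.50 for beat and side, from -0.52 to 0.58 for all cell surface genes and from -0.81 to 1.30 for cyclic AMP signalling. For KC minus PN, cyclic AMP signalling went from 1.51 to -0.76, and for KC minus DN the ecdysone response list went from -0.64 to 0.63. The value of -0.64 lay inside its matched range (-1.04 to 0.41). Against lists also matched on exon length, the adult values of 0.87, 0.51, 0.50, 0.58 and -0.76 for the Kenyon cell, dpr and DIP, beat and side, all cell surface and KC minus PN cyclic AMP lists lay inside the range as well. Among marker genes, dnc went from 1.52 to -2.22 for KC minus PN and from -1.30 to 3.12 for PN minus DN, elav from -1.34 to 1.31 for PN minus DN, and repo from 1.22 to -1.07 for PN minus DN.

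As a list, cell surface genes were low in KC against both other populations at both stages. Gene length is argued against as the whole cause: lists matched on expression and exon length held at most 34 such genes at 45 h APF and 25 in the adult, where 66 and 54 were found. At 5 FPKM, a lower detection of all genes in KC is argued against too. KC detected 91.3% as many genes as DN at 45 h APF and 95.8% in the adult, against 52.8% and 63.2% of cell surface genes. At 1 FPKM the gap was too narrow for the margin used, and the question stays open there. KC then had 75.7% and 77.6% as many cell surface genes as DN, and 7901 against 8646 and 7746 against 8331 of all genes. The share of all genes covers genes of every kind, so it cannot tell whether neuronal genes were lower in KC in general. Pan-neuronal genes had medians of -0.56 for KC minus PN and -1.07 for KC minus DN at 45 h APF, and -2.06 and 0.19 in the adult. The values of -1.07 and -2.06 lay below their matched ranges, and the others inside. For adult KC minus PN, medians were -1.58 for channels and -1.59, -1.41 and -0.92 for acetylcholine, GABA and glutamate, and monoamine receptors. The cell surface median there was -1.45, so that comparison does not set cell surface genes apart from other neuronal genes. At 45 h APF those 4 medians were -0.29, -0.23, 0.43 and -0.14, beside -1.08 for cell surface genes. Glial RNA in the PN sample stays open at 45 h APF, where the glia list had a median of -2.45 for KC minus PN, and is argued against in the adult, where the median was 0.20. With PN left aside, 93 of 139 genes at 45 h APF and 60 of 133 in the adult were at least 2-fold lower in KC than in DN. That comparison is not free of glial RNA either, since the glia list had medians of -0.94 and -1.47 for KC minus DN, and glial RNA in DN was not tested. Not every family lay below its matched range in adult KC against DN. Medians inside their ranges were -0.04 for leucine-rich repeat genes, -0.07 for teneurin, neurexin and neuroligin genes and 0.03 for guidance genes. The cadherin median of -0.98, with 3 of 7 at least 2-fold lower, was inside too, but the range of so small a list is wide (-1.15 to 0.62). The lowest were -1.99 for beat and side and -1.70 for dpr and DIP. A difference between the cell types themselves may account for the pattern, as a hypothesis that the single columns cannot test against variation between animals. Each column is a bulk value of a sorted population, so the counts do not give the number of cell surface genes in a single cell. How mixed each population was in its cell types was not measured.

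Glial genes stood higher in PN than in KC and DN at 45 h APF, and 2 of the fixed list, ltl and wrapper, are also cell surface genes. Glial RNA in the PN sample is a candidate explanation, tested on 13 glial genes outside the fixed list: the smaller of their medians was 1.24 (PN minus DN, 8 of 13 at least 2-fold higher), with 2.19 for PN minus KC, above matched ranges that ended at 0.35 and 0.54. The most abundant were kune at 192 FPKM in PN, 130 in DN and 73.8 in KC, and pck at 153, 33.4 and 105, and 8 of the 13 reached 5 FPKM in KC, so the other columns hold such transcripts as well. In the adult the medians were -0.55 and -0.69. The glial genes wrapper (14.1 in PN, 43.0 in DN) and CG4797 (15.6 and 23.4) went the other way. The sort on tomato selects against unlabeled glia, but its purity was not measured. Expression of these genes by the neurons themselves was not tested.

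Between the stages, limma called 2217 genes. Of the 10 splits of the 6 columns into 3 and 3, only the real split (1 split) gave as many, and the highest of the others gave 0. With 10 splits the share cannot go under 0.05. In every other split the stage difference entered the residual spread, which lowers the calls by construction. The splits therefore cannot decide whether the calls arose by chance.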

How the results depend on the processing

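No paired analysis was possible because the deposited adult columns are averages and pupal libraries are single. Not run, as the replicates are not in the file, were leaving out each adult library, a fit of only the 4 libraries of a comparison, and a replicate block. Protein-coding genes only, genes above 0 in all columns and the weight for adult means were chosen after seeing the data, and that weight cannot move the stage count by its construction. Without a count table the low end is limited by depth, which the pseudocounts address. Genes at least 4-fold apart at 45 h APF became 1293 and 355 for KC minus PN, 1201 and 248 for KC minus DN, and 652 and 154 for PN minus DN with pseudocounts of 0.1 and 5. In the adult they became 434 and 307 for KC minus PN and PN minus DN with 5, and 988 and 276 for KC minus DN with 0.1 and 5. A larger pseudocount shrinks all differences by construction. The cell surface medians became -0.61 and -1.02 for KC minus PN and KC minus DN at 45 h APF and -0.46 for adult KC minus DN with 5, and the last was -0.38 with no filter and with a mean of at least 5 FPKM. In the limma fit, KC minus PN gave 28 genes with a pseudocount of 5, 0 with no filter, 43 with quantile normalization, 33 with no trend, 110 with genes above 0 and 115 with adult means weighted 2. KC minus DN gave 17, 1, 36 and 38 under the first 4 of these and 101 for protein-coding genes. PN minus DN gave 1 with a pseudocount of 5, no filter, no trend or genes above 0, the last because noe is left out. The stage gave 617 with no filter. For the cell surface list, camera gave 0.0694 for the stage with no filter, and for KC minus PN, KC minus DN and the stage 0.521, 0.466 and 0.703 with an estimated correlation and 0.236, 0.15 and 0.717 with fry. Leaving out 1 column gave 0 to 51 genes for KC minus PN, 0 to 143 for KC minus DN, 0 to 7 for PN minus DN and 0 to 1597 for the stage. The cell surface camera p ranged from 0.00018 to 0.606 for PN minus DN, with the direction reversed without adult PN (0.00577) and adult DN (0.000513), and from 8.96e-05 to 0.181 for the stage. With 1 column out, 1 residual degree of freedom remains. Otherwise the cause was not tested. Detection of cell surface genes at 1 or 20 FPKM kept KC below PN and DN at both stages. KC had 75.7% and 77.6% as many as DN at 1 FPKM (45 h APF and adult), and 43.5% and 70.9% at 20 FPKM. The gap to the share of all genes was narrower at 1 FPKM than at 5 FPKM. Upper quartile scaling kept each total within 1.5 times and each cell surface camera p on its side, but turned the fitted cell surface median for PN minus DN from 0.06 to -0.02, and it brought the stage split to 950 and 897. Of the values for single genes within a stage, 1132 stayed within limits and 51 moved. Of those in the fit, 515 stayed and 90 lost their call, and with 1 column left out 135 stayed and 231 lost it.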

Other observations

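The tests of the w region and of the added glial genes were set out before their results were seen. Genes of the activity-regulated list were lower in KC than in PN at 45 h APF, with a median of -1.07 and 5 of 9 at least 2-fold lower, led by Arc2 (3.72 against 17.4 FPKM). Over the stages limma called 4 of 10 of them higher in the adult, such as sr (-3.70, adjusted p = 0.0089) and Hr38 (-3.38, adjusted p = 0.0119), and 1, Arc1 (2.06, adjusted p = 0.0227), at 45 h APF, or 4 and 3 when adjusted over the list alone. The median was -0.91, with a camera adjusted p of 0.0471 and an adjusted p of 0.677 with an estimated correlation. Of ecdysone response genes, mamo was at 81.5 FPKM in adult PN, 13 in KC and 5.10 in DN, and over the stages 4 of 15, such as ftz-f1 (-2.97, adjusted p = 0.0211), were higher in the adult and 1, Hr4 (3.03, adjusted p = 0.0119), at 45 h APF, or 9 and 2 when adjusted over the list alone. That list had a median of -1.35 and a camera adjusted p of 0.00228, and its adjusted p was 0.677 with an estimated correlation. Of 11 acetylcholine receptor genes 7 were lower in adult KC than in PN, with nAChRalpha3 at 0.410 against 47.7 FPKM. Of 13 GABA and glutamate receptor genes 8 were, with GABA-B-R3 at 0.496 against 12.8. Monoamine receptors went both ways there, with 5-HT7 at 0.241 against 18.7 and Dop1R2, a dopamine receptor of learning, at 15.8 against 1.11. Of 15 cell cycle genes 11 were at least 2-fold lower in KC than in DN at 45 h APF, such as PCNA (1.30 against 14.8), but their median of -1.36 lay inside the range of lists matched on exon length (-1.41 to 0.03), and the median of -1.0 for KC minus PN inside its matched range (-1.14 to 0.25). The clock list was near 0 for KC minus PN (-0.06 at both stages), where quantile normalization gave 0.28 and 0.50. Genes of oxidative phosphorylation had medians of 0.16 and -0.31 for KC minus PN, with 2 of 63 and 1 of 62 at least 2-fold lower and none higher. The first lay inside its matched range (-0.05 to 0.23), and the second at the end of its range (-0.31 to 0.34) and below that of lists also matched on exon length (-0.04 to 0.66). In the fit for KC minus PN, cyclic AMP signalling had a median of -0.27 and a mean of 0.21, and neuropeptides a median of 0.06 and a mean of -0.21, and neither list was called by camera (adjusted p = 0.69 and 0.715).

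Genes of tissues outside the central brain were kept in part, with 5 of 8 muscle genes at 45 h APF, such as Act87E (5.10, 0.0249 and 116 FPKM in KC, PN and DN), and 4 of 8 fat body genes. Of the photoreceptor list norpA was kept at 45 h APF (4.53 FPKM in DN) and Arr2 in the adult (9.73 in DN). Fat body genes were led by Lsp2, at 10.2, 10.2 and 26.6 FPKM in KC, PN and DN at 45 h APF. Of hemocyte genes Pxn was at 320, 152 and 98.2 FPKM there. Among antimicrobial peptides, 3 of 5 were higher in KC than in PN at 45 h APF, with Def at 12.0 against 3.37.

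The gene w was at 306, 352 and 9.95 FPKM in KC, PN and DN at 45 h APF and at 195, 169 and 7.49 in the adult. Since flies with transgenes usually carry a w marker gene, the w marker next to the drivers and reporters may be read out in the cells that express them. That hypothesis needs the neighbors of w to stay level. The median absolute log2 difference of its 6 nearest genes with a mean of at least 1 FPKM was 0.61. A value of at least 2 had been set beforehand as the mark of a change of the whole region. Syx4 and CG3603 stood under 1 FPKM in all adult columns, so they could show only small differences there, which lowers the median. Not every neighbor stayed level: kirre differed between KC and DN by -2.01 and -1.53, rst by -1.77 and -1.62, and CG3603 between PN and DN by 1.57 at 45 h APF. The test does not separate a transgene from regulation of w alone. The pigment gene y, also on the X chromosome, at 60.9, 2.02 and 0.151 FPKM at 45 h APF and 138, 2.15 and 1.08 in the adult, was called higher in KC than in PN (4.91, SE 0.51, adjusted p = 0.0212 in limma) and in DN (5.91, SE 0.51, adjusted p = 0.0234), and no cause of it was tested.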
